A study of Mus musculus with 12 samples.

How the data were processed

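Gene expression was measured on Affymetrix mouse gene arrays, 1 array per sample, in bone marrow plasma cells of donor origin that bound the hapten NP. The sorted cells lacked B220, Ly6g, CD11b and the recipient's CD45.1 and carried CD138 and the donor's CD45.2. The labels give the genotype and replicate number of all 12 samples, 6 wild-type and 6 Zbtb32-/-, and the series text calls them biological replicates. Per the labels' protocols, total RNA was prepared with a Nucleospin RNA XS kit, amplified with the WT Pico kit and labelled with biotin. Amplification from few cells can widen the spread between arrays.

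The deposited values are log2 expression values per probe set, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, with versions not given in the sources used here. RMA subtracts background, makes the distributions of the arrays alike and summarises the probes of a probe set. It compresses low values and hides any difference in total RNA between samples. Whether all 12 arrays were normalized together is not stated in the sources used here. Raw intensities and detection calls were not used here. The values ran from 2.33 to 14.33, with no missing values and 0 pairs of identical columns, and every column of the table belongs to a labelled sample.

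Gene names came from the platform annotation paired with the probe sets. Of 35556 probe sets, 21789 name exactly 1 gene, 1621 name several genes and 12146 are unnamed here. The Entrez identifiers of 21698 of the single-gene probe sets were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed through it. That table also gave the neighbours of Zbtb32, and no coordinates are printed because the deposited table names no genome build. For the main tests a gene was represented by its single-gene probe set with the highest mean over the 12 arrays, which gave 19938 genes. Genes with a mean at or below the 25th percentile of such probe sets, 5.49 on the log2 scale, were left out, which left 14993. Where a gene has several probe sets they can disagree, as those of Ighm did.

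Differences are Zbtb32-/- minus wild type on the log2 scale. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A total of 31 gene lists with 1004 entries was fixed beforehand, of which 880 entries matched a single-gene probe set, 7 of them through a synonym. The 28 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over lists. They were tested again with an estimated correlation, with fry, which tests whether a list's genes move one way and compares them with no other genes, and with a two-sided exact permutation of the list mean per array over all 924 assignments. The error of a list difference is the standard error over arrays. Level-matched lists were 10000 random lists of the same size drawn from genes of like mean level. Confidence intervals are 95%.

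The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Zbtb32, the genes with the largest changes past the threshold and, because fewer than 10 passed, the 10 genes of each direction with the smallest p. Predicted genes, receptor families, small RNAs and variable segments were counted but not named by rank. For each list the 2 members with the smallest p were named when none passed, and for lists of other cell types also the 2 with the highest level. Ighm, Ighg1 and Igkc were named where measured by a single-gene probe set.

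The gene and list tests were tested on simulated data with the spread of these arrays, for 14993 genes and 6 against 6 arrays, with 200 genes changed. Of genes changed by 0.5, 1 and 2 on the log2 scale, 34.3%, 74.6% and 98.5% were recovered, and 13 of the 151 genes called were unchanged ones. A simulated shift of 0.3 in the mitosis list, with genes varying independently, was estimated as 0.314.

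The alternatives were renewed quantile normalization, median centring, no filter and a stricter filter on low values, the mean of a gene's probe sets, other variance settings, array weights, the replicate number as a block, a covariate for markers of other cells, a fold threshold and leaving out each array. After the data were seen, further alternatives were added: replicates 1 to 3 against 4 to 6 as a block and separately, a sex covariate, an erythroid covariate, leaving out wild-type replicates 2 and 6, and all probe sets of the table. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 joined the tables and drew the plots. Probe sets that name several genes entered no gene test.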

Results

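Plasma cells that arose in a recall response were compared between 2 genotypes on gene expression arrays. Splenocytes of wild-type or Zbtb32-/- donor mice immune to NP-CGG, a hapten coupled to a carrier protein, had been moved into recipients that differ from the donors in the CD45 allele, and the recipients were challenged with the antigen. After 7 days, antigen-binding plasma cells of donor origin were sorted from the marrow by their surface markers. The series title speaks of memory B cells, while the labels of all 12 samples give plasma cells of the bone marrow, and the labels were followed here. Each genotype had 6 arrays, which the series text calls biological replicates. Zbtb32 encodes a zinc finger transcription factor of the BTB family, and the comparison asks how its absence alters the transcripts of these cells. The median log2 value per array lay between 6.28 and 6.43, and the correlation between pairs of arrays across probe sets ran from 0.914 to 0.984. Wild-type replicates 2 and 6 had the lowest mean correlation with the other arrays, at 0.933 and 0.938. The arrays also differed by their replicate number: between replicates 1 to 3 and replicates 4 to 6, a grouping chosen after the data were seen and not named as a batch in the labels, 943 genes passed an adjusted p of 0.05 with limma. Each of these sets holds 3 arrays of each genotype. The number of arrays limits the precision: the 95% interval of a gene's difference had a median width of 0.311 log2 units to either side.

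The single probe set of Zbtb32 gave 6.67 ± 0.16 in wild-type cells and 6.56 ± 0.10 in Zbtb32-/- cells (log2 RMA value, SD, n = 6 each). The difference, Zbtb32-/- minus wild type, was -0.11 (95% interval -0.31 to 0.09, two-sided exact permutation p = 0.173). It was 0.02 over replicates 1 to 3 and -0.24 over replicates 4 to 6. The deleted part of the gene is not given in the sources used here, so this probe set can neither check the genotype labels nor contradict them. Its mean level lay at percentile 51.8 of the probe sets that name 1 gene.

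No gene differed between the genotypes after adjustment: of 14993 genes tested with limma, 0 were higher and 0 were lower in Zbtb32-/- cells, and the smallest adjusted p was 0.933. With the 2 replicate sets as a block the count was also 0. At an unadjusted p under 0.05 there were 642 genes, 425 with a positive and 217 with a negative difference, where chance gives 749.65. This number ran from 458 to 1416 on leaving out single arrays, above the chance value only without wild-type replicate 3 (1416), wild-type replicate 1 (1005) or Zbtb32-/- replicate 6 (968), and it was 341 over replicates 1 to 3 and 1057 over replicates 4 to 6. For 95.3% of the genes the 95% interval excluded a 2-fold change in either direction, and for 73.4% it excluded a 1.5-fold change. These shares include genes of low level, where RMA compresses differences, so they do not show that such transcripts were unchanged. Among the 230 genes within 10 Mb of Zbtb32, 0 passed the adjusted threshold and 10 had an unadjusted p under 0.05, a share of 4.35% against 4.28% elsewhere (two-sided Fisher's exact test, p = 0.870).

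The smallest unadjusted p-values are given here as values, since none of these genes passed. On the positive side were Arv1, a factor of sterol transport (0.87, SE 0.17), Slc25a43, a mitochondrial carrier (0.60, SE 0.13), Mtbp, an Mdm2-binding protein (0.91, SE 0.21), and Bid, a pro-apoptotic member of the Bcl2 family (0.63, SE 0.15). Tubg1, the gamma tubulin of the spindle poles, differed by 0.51, Blm, a DNA helicase, by 0.57, and Spc25, a kinetochore protein, by 0.52. Entpd4, Mrps27 and Fam122b differed by 0.85, 0.82 and 0.41. On the negative side were Sesn3, a stress-induced sestrin (-0.84, SE 0.21), Pdxp (-0.55, SE 0.14), Tbcel (-0.42, SE 0.12) and Crebl2 (-0.34, SE 0.09). The cytokine genes Lif and Lta differed by -0.33 and -0.23, and Gnmt, Lipt2, Hoxb13 and Sox18 by -0.31, -0.28, -0.27 and -0.26. These 6 genes lay low on the arrays, with means over the 12 arrays of 5.58 to 6.01, where the filter on low values lay at 5.49.

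Genes of cell division had positive differences as a group, which passed camera with a preset correlation but not with an estimated one (adjusted p = 0.571), by fry (0.342) or by exact permutation (0.424), and no single member passed. The G2 phase and mitosis list had a mean of 8.58 ± 0.26 in wild-type and 8.90 ± 0.09 in Zbtb32-/- arrays (log2, SD, n = 6 each), a difference of 0.32 (SE 0.11) or 1.25-fold. All 44 measured members had a positive difference, 16 of them at an unadjusted p under 0.05, and 0 passed over all genes or adjusted over the list alone. The DNA replication and S phase list differed by 0.25 (SE 0.09), with 40 of 43 members positive, 11 at an unadjusted p under 0.05 and 0 passing over all genes or adjusted over the list alone. In both lists 6 of 6 Zbtb32-/- arrays lay above the wild-type mean. Among the members, Spc25 differed by 0.52 and Cdca8, a subunit of the chromosomal passenger complex, by 0.53. Tyms, the thymidylate synthase, differed by 0.62 and Rfc4, a subunit of the clamp loader, by 0.47. The limma camera test with a preset correlation gave adjusted p = 4.67e-17 for mitosis and 7.97e-10 for replication. Each had adjusted p = 0.571 with an estimated correlation, and the two-sided exact permutation p of the list mean was 0.0281 for mitosis and 0.0303 for replication (adjusted over 28 lists, 0.424 for each). Markers of erythroid cells differed by 0.27 (SE 0.24), with adjusted p = 0.0385 by camera and 0.760 with an estimated correlation. The mitosis difference was 0.19 over replicates 1 to 3 and 0.45 over replicates 4 to 6, and the replication difference was 0.25 in each set. Without wild-type replicates 2 and 6, left out after the data were seen, the differences were 0.21 and 0.16.

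**Figure D1:**
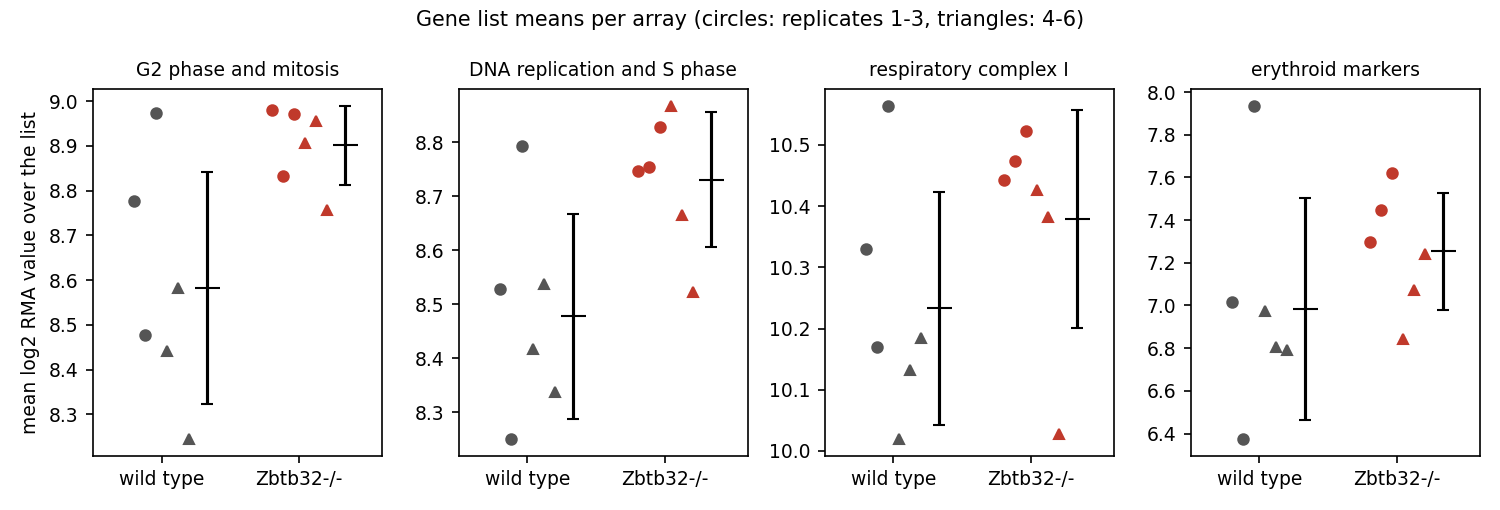
Mean log2 RMA value over the measured members of 4 gene lists on the vertical axis, 1 point per array, for wild-type and Zbtb32-/- plasma cells (6 each), with the mean and SD beside the points. The Zbtb32-/- mean of the mitosis list is 8.90 against 8.58, and wild-type replicates 1 and 3 lie within the range of the Zbtb32-/- arrays.

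Genes of the mitochondria had smaller positive differences. Respiratory complex I differed by 0.15 (SE 0.11), with 34 of 35 members positive, and complexes II to V by 0.14 (SE 0.10), with 37 of 40 members positive. The mitochondrial ribosome list differed by 0.18 (SE 0.11, 68 of 75 members positive) and the TCA cycle list by 0.15 (SE 0.11, 16 of 18). The list for mitochondrial import, dynamics and biogenesis differed by 0.10 (SE 0.09, 27 of 36). Of the members, Ndufb7 and Ndufa7 of complex I differed by 0.25 and 0.44, Uqcr10 of complex III by 0.33, and Atp5j2 of the ATP synthase by 0.16. Mrps27 and Mrps25 of the small mitochondrial ribosomal subunit differed by 0.82 and 0.52, Sucla2 and Idh3g of the TCA cycle by 0.47 and 0.19, and the import proteins Timm50 and Tomm7 by 0.49 and 0.20. In these 5 lists 0 members passed over all genes and 0 passed adjusted over the list alone. Camera with a preset correlation gave adjusted p = 8.09e-06 for complex I, 2.59e-07 for complexes II to V, 1.47e-07 for the mitochondrial ribosome, 0.00198 for the TCA cycle and 0.0336 for import. With an estimated correlation the adjusted p was 0.712 for the first 4 and 0.760 for import. The difference in complex I was 0.12 over replicates 1 to 3 and 0.17 over replicates 4 to 6, and in complexes II to V 0.12 and 0.15. In the same order the mitochondrial ribosome gave 0.15 and 0.20, the TCA cycle 0.08 and 0.21 and import 0.06 and 0.13. Over all genes the difference grew with the level, from a median of -0.05 in the lowest decile of mean level to 0.13 in the highest. Against 10000 random lists of the same size and level, the median of complex I lay at percentile 72.6, that of complexes II to V at 79.5, the TCA cycle at 88.9 and import at 44.7. The mitochondrial ribosome lay at percentile 99.2, above the central 95% of its matched lists, and mitosis and replication both lay at percentile 100. These percentiles do not allow for genes that vary together between arrays, and lists of other cells and of stress lay as far out: erythroid markers at 99.99, neutrophil markers at 99.8, monocyte markers at 0, immediate early genes at 0.16 and MHC class II genes at 0.84. Renewed quantile normalization brought the 2 respiratory differences to 0.08 and 0.07, and the import list lost its camera call without any 1 of wild-type replicates 1, 4, 5 and 6 and Zbtb32-/- replicates 1, 2, 3 and 4, at differences from 0.07 to 0.11. It was 0.15 without wild-type replicate 3 and 0.16 without Zbtb32-/- replicate 6, and the TCA cycle difference was 0.09 without wild-type replicate 4. Complex I was lowest in wild-type replicates 4 and 5 (10.02 and 10.13) and Zbtb32-/- replicate 6 (10.03). The TCA cycle list was lowest in these arrays and wild-type replicate 6. These arrays had the highest mean over the neutrophil, monocyte, erythroid and T and NK lists, at 8.12, 8.07, 8.40 and 7.92 in this order.

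**Figure D2:**
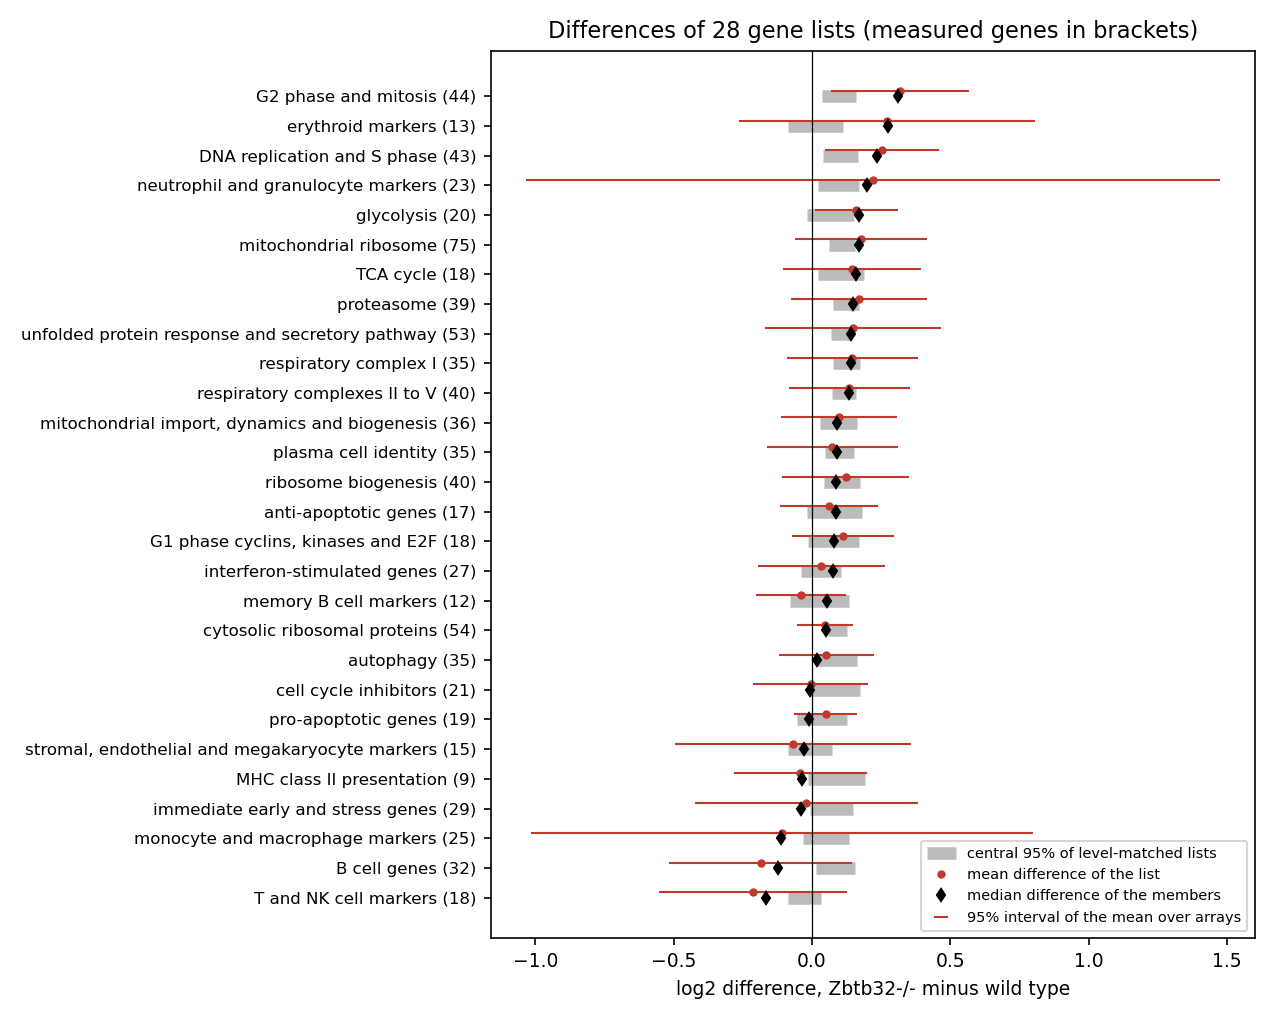
Log2 difference between Zbtb32-/- and wild-type arrays on the horizontal axis for 28 gene lists, as the mean over the list with its 95% interval over arrays and as the median over members, with the central 95% of 10000 level-matched random lists in grey. The medians of mitosis, 0.31, and replication, 0.24, lie above their grey ranges, which end at 0.16 and 0.17.

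Lists for protein synthesis and secretion, the main task of a plasma cell, and for the proteasome and glycolysis also had positive differences. The unfolded protein response and secretory pathway list differed by 0.15 (SE 0.14), with 52 of 53 members positive, among them Ero1a, an oxidase of the endoplasmic reticulum, at 0.48 and the chaperone Canx at 0.22. The proteasome list differed by 0.17 (SE 0.11, 36 of 39), with Psmc3 at 0.32 and Psmd8 at 0.24. Glycolysis differed by 0.16 (SE 0.07, 17 of 20), with the glucose transporter Slc2a1 at 0.41 and Ldha at 0.29. Ribosome biogenesis differed by 0.12 (SE 0.10, 32 of 40), with Utp15 at 0.53 and Nop56 at 0.31, and cytosolic ribosomal proteins by 0.05 (SE 0.05, 43 of 54), with Rpl13 at 0.17 and Rpl4 at 0.07. In these 5 lists 0 members passed over all genes and 0 passed adjusted over the list alone. Camera with a preset correlation gave adjusted p = 1.20e-05 for secretion, 2.59e-07 for the proteasome, 0.00633 for glycolysis, 0.0136 for ribosome biogenesis and 0.00329 for ribosomal proteins. With an estimated correlation the adjusted p was 0.712 for the proteasome and glycolysis and 0.760 for the others. Against level-matched lists, glycolysis lay at percentile 99.1, secretion at 96.6, the proteasome at 83.4 and ribosome biogenesis at 25.7, and cytosolic ribosomal proteins lay at percentile 1.85, below genes of like level. Plasma cell identity genes differed by 0.07 (SE 0.11, camera adjusted p = 0.294), with Jchain at -0.11, Il6ra at 0.26 and 0 members passing over all genes or adjusted over the list alone. The secretion difference was 0.02 over replicates 1 to 3 and 0.27 over replicates 4 to 6. In the same order the proteasome gave 0.11 and 0.23, glycolysis 0.11 and 0.21, ribosome biogenesis 0.06 and 0.18, ribosomal proteins 0.05 and 0.04 and plasma cell identity -0.01 and 0.16. The plasma cell identity list passed camera with the preset correlation without wild-type replicate 1, at 0.14 (adjusted p = 0.0154), and without Zbtb32-/- replicate 6, at 0.13 (adjusted p = 0.0380). With an estimated correlation 0 lists passed camera in these settings (smallest adjusted p = 0.637 and 0.391). The plasma cell identity difference was 0.01 without wild-type replicate 4. The secretion list lost its camera call without wild-type replicate 4, at 0.06, and ribosomal proteins without Zbtb32-/- replicate 4, at 0.03. Ribosome biogenesis lost it without wild-type replicate 5 or 6 or Zbtb32-/- replicate 2 or 4, at 0.09 to 0.10, and was 0.19 without Zbtb32-/- replicate 6. Ribosomal proteins differed by 0.07 without wild-type replicate 3 and by 0.08 without Zbtb32-/- replicate 6. The secretion list was lowest in wild-type replicates 4, 5 and 6 (10.54, 10.80 and 10.82) and Zbtb32-/- replicate 6 (10.75). So were the proteasome, ribosome biogenesis and plasma cell identity lists. The same arrays had the highest mean over the neutrophil, monocyte, erythroid and T and NK lists (8.12, 8.07, 7.92 and 8.40). In these arrays low means of the lists thus went with high markers of other cells, a link that was not tested. Wild-type replicate 2 went against it, with the lowest mean of such markers, 6.76. Its proteasome, ribosome biogenesis and plasma cell identity means were the next lowest, at 10.26, 8.65 and 9.73.

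Genes of B cells and of T and NK cells had negative differences as lists, which passed camera with a preset correlation but not with an estimated one (adjusted p = 0.603 and 0.712) or by exact permutation (unadjusted p = 0.236 and 0.186). The B cell list differed by -0.18 (SE 0.15), with 8 of 32 members positive, and the T and NK cell list by -0.21 (SE 0.15), with 3 of 18 positive. Of the B cell genes, Bach2, a repressor of plasma cell differentiation, differed by -0.70 and the chemokine receptor Ccr7 by -0.44. Of the T and NK list, Il7r differed by -1.04 and Cd5 by -0.19, both of which B lineage cells can also express, and Cd2 by -0.002. In both lists 0 members passed over all genes and 0 passed adjusted over the list alone. Camera adjusted p was 0.000181 for the B cell list and 0.00114 for the T and NK list with the preset correlation. The B cell difference was 0.04 over replicates 1 to 3 and -0.41 over replicates 4 to 6, -0.29 without wild-type replicate 2 and -0.12 without wild-type replicate 5. The T and NK difference was -0.03 over replicates 1 to 3 and -0.40 over replicates 4 to 6, and that of Il7r was -0.03 and -2.05. The T and NK list lost its call without wild-type replicate 6, at -0.08. The B cell list was highest in wild-type replicates 4, 5 and 6 (8.82, 8.93 and 8.80). Their means over the neutrophil, monocyte, erythroid and T and NK lists were also high (8.12, 8.07 and 7.92). Zbtb32-/- replicate 6 had the highest such mean, 8.40, but a B cell list mean of 8.55.

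Markers of other bone marrow cells differed between arrays more than between genotypes. Neutrophil genes were abundant in both genotypes: S100a9 averaged 12.55 and Ngp 12.25 over the 12 arrays, although the sort excluded cells with Ly6g and CD11b. The neutrophil list differed by 0.22 (SE 0.56, camera adjusted p = 0.447) and the monocyte and macrophage list by -0.11 (SE 0.41, adjusted p = 0.184), with Cd68 at -0.51 and Cd14 at -0.43. Mcpt8 and Prss34, genes of basophils in the neutrophil and granulocyte list, differed by -0.75 and -0.37, and by -0.07 and 0.04 without wild-type replicate 4. In the monocyte list the genes with the highest values were Bst2, at a mean of 11.12, and Cybb, at 10.16. Bst2 is also in the list of interferon-stimulated genes, so its value does not mark monocyte RNA alone. The monocyte difference was 0.36 over replicates 1 to 3 and -0.57 over replicates 4 to 6, and the erythroid difference was 0.35 and 0.19. Of the erythroid list, 12 of 13 members were positive. The member with the highest value, Car1, averaged 9.18, with a difference of 0.98 (SE 0.58), or 0.49 without wild-type replicate 2. The erythroid list's camera call was lost without any 1 of wild-type replicates 1, 2, 5 and 6 and Zbtb32-/- replicates 2, 3 and 6, at differences from 0.15 to 0.28, and the list's difference was 0.46 without wild-type replicate 3. Stromal, endothelial and megakaryocyte markers differed by -0.07 (SE 0.19, adjusted p = 0.147), with Pecam1 at -0.32, Kdr at -0.22 and Sparc at 0.09. On leaving out single arrays the differences ran from -0.12 to 0.44 for neutrophil, -0.32 to 0.13 for monocyte and -0.19 to 0.03 for stromal markers. In these 4 lists 0 members passed over all genes and 0 passed adjusted over the list alone.

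Lists for cell survival, antigen presentation and memory did not pass the camera test. Pro-apoptotic genes differed by 0.05 in the mean (SE 0.05, camera adjusted p = 0.561) and by -0.01 in the median. Of 19 members 1, Bid, passed when adjusted over the list alone (limma adjusted p = 0.0155), against 0.933 over all genes. That adjustment was made within each of the 28 lists and does not allow for their number, so 1 such gene is little evidence. Diablo of the pro-apoptotic list differed by 0.32. Anti-apoptotic genes differed by 0.06 (adjusted p = 0.525), with Xiap at 0.35 and Bcl2 at 0.15. Cell cycle inhibitors differed by -0.004 (adjusted p = 0.525), with Cdkn1b at -0.23 and Cdkn2c at 0.28, and G1 phase genes by 0.11 (adjusted p = 0.0958), with Cdk7 at 0.54 and Cks1b at 0.31. Memory B cell markers differed by -0.04 in the mean and 0.06 in the median (adjusted p = 0.770), with Nt5e at -0.27 and Kmt2a at 0.27. MHC class II genes differed by -0.04 (adjusted p = 0.369), with Ciita at -0.19 and H2-Ab1 at -0.04. Autophagy genes differed by 0.05 (adjusted p = 0.561), with Atg4a at 0.86 and Atg14 at 0.34. Interferon-stimulated genes differed by 0.03 (adjusted p = 0.923), with Oasl1 at -0.24 and Zbp1 at 0.28, and immediate early genes by -0.02 (adjusted p = 0.261), with Dusp2 at -0.33 and Ier5 at 0.28. On leaving out single arrays the differences ran from 0.06 (without wild-type replicate 2) to 0.17 for G1 phase genes, 0.02 to 0.10 for autophagy, 0.03 to 0.10 for anti-apoptotic and 0.03 to 0.08 for pro-apoptotic genes, and -0.09 to -0.01 for memory B cell markers. They ran from negative to positive for cell cycle inhibitors (-0.05 to 0.05), MHC class II (-0.08 to 0.04), interferon-stimulated genes (-0.03 to 0.10) and immediate early genes (-0.12 to 0.05). In these 9 lists 0 members passed over all genes, and apart from Bid 0 passed adjusted over the list alone.

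The lists with under 5 measured members were not tested as sets. Of the immunoglobulin constant regions, Igha differed by 0.54 (SE 0.63) and Ighg3 by -0.12 (SE 0.21). The Igha difference was 1.11 without wild-type replicate 4, 0.24 without Zbtb32-/- replicate 6 and 0.33 to 0.35 without any 1 of wild-type replicates 2, 3 and 6. The probe set used for Ighm gave 9.61 ± 0.06 in wild-type and 9.56 ± 0.08 in Zbtb32-/- arrays (SD, n = 6 each). The mitochondrially encoded COX2 and ND3 differed by -0.15 (SE 0.14) and 0.14 (SE 0.34). The sex-linked Xist and Kdm5d differed by 1.39 (SE 1.17) and -0.62 (SE 0.36). None of these 7 genes passed over all genes with limma.

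In all, 13 of the 28 tested lists were higher and 2 were lower at an adjusted p under 0.05 by camera with the preset correlation. With an estimated correlation 0 lists passed (2 at an unadjusted p under 0.05), by fry 0 passed (smallest adjusted p = 0.342, 2 unadjusted), and by the exact permutation test of list means 0 passed (smallest adjusted p = 0.424, 2 unadjusted).

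Some probe sets that the annotation used here does not name separated the genotypes. When all 35556 probe sets of the deposited table were tested, a step added after the data had been seen, 7 were lower and 0 higher in Zbtb32-/- cells at an adjusted p under 0.05 with limma, and 1346 had an unadjusted p under 0.05. Of the 7, 4 held identical values, so that they carry 4 distinct signals, and 0 of the 7 has a gene name here. Probe set 10551998 fell from 12.47 ± 0.19 to 11.21 ± 0.16, or 2.39-fold, and probe set 10415081 fell from 11.92 ± 0.31 to 9.43 ± 0.46, or 5.61-fold (log2, SD, n = 6 each; limma adjusted p = 0.000348 for each). Both were chosen after their values had been seen. Every wild-type array lay above every Zbtb32-/- array in each of the 4 signals. The mean over the 4 signals differed by -2.12. All 7 remained past the threshold on leaving out any 1 array, and probe set 10415081 differed by -2.94 over replicates 1 to 3 and by -2.04 over replicates 4 to 6.

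**Figure D3:**
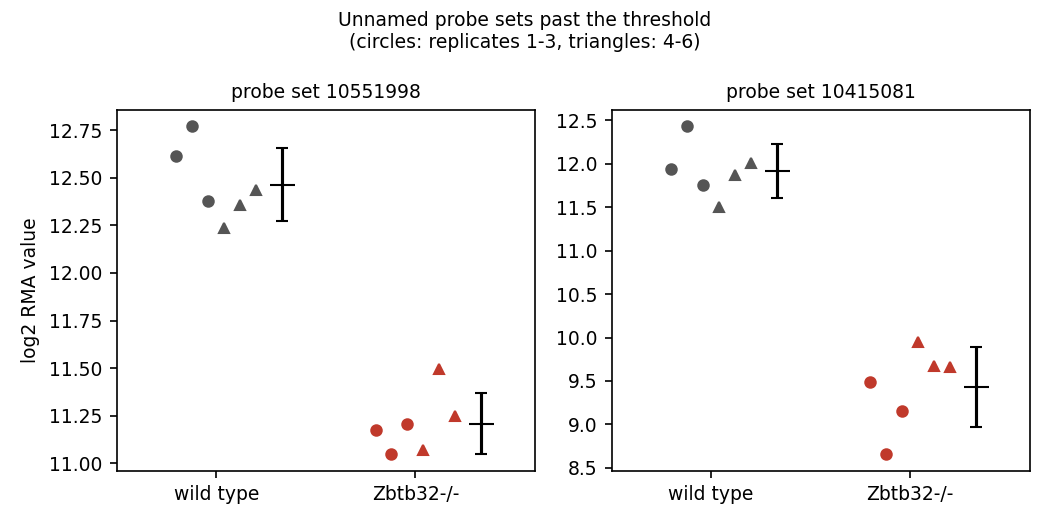
Log2 RMA value on the vertical axis of 2 probe sets without a gene name here, 1 point per array, for wild-type and Zbtb32-/- plasma cells (6 each), with the mean and SD beside the points. The wild-type and Zbtb32-/- arrays do not overlap: the lowest wild-type value of probe set 10415081 is 11.51 and the highest Zbtb32-/- value is 9.95.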

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

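The values below were picked by a rule for arrays far from the other 5 of their group, applied to each named gene and each list mean. Chance flags about 1 in 20 such groups, which gives 11.6 of the 232 tested, and 20 were found. All values are log2 RMA values. The test of dilution and that of the immunoglobulin variable probe sets were chosen after the results were seen, as were both tests of the unnamed probe sets, the split count for genes and the splits balanced over the replicate sets.

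Zbtb32-/- replicate 6 gave 7 of the 20. It was low in the list means of plasma cell identity (9.54, others 9.78 to 9.90), the proteasome (10.12, others 10.45 to 10.60), respiratory complex I (10.03, others 10.38 to 10.52) and cytosolic ribosomal proteins (11.998, others 12.18 to 12.24). It was also low in Nop56, at 9.23, and Pecam1, at 7.42, and high in Cybb, at 11.24. Wild-type replicate 2 gave 4: Ngp was low, at 9.15 against 11.99 to 13.01, Rpl13 was low, at 11.95, Jchain was high, at 13.94, and Xist was high, at 8.87. Wild-type replicate 4 gave 3: Mcpt8 was 9.66 against at most 5.97 in the other wild-type arrays, Prss34 was 8.30 against at most 5.92, and Igha was 12.26 against at most 9.54. Zbtb32-/- replicate 2 was high in Dusp2, at 8.90, and Ighm, at 9.73. Zbtb32-/- replicate 5 was high in Mcpt8, at 5.94, and Ero1a, at 9.11. Zbtb32-/- replicate 4 was high in Tyms, at 10.28, and wild-type replicate 3 in the cytosolic ribosomal list, at 12.26.

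As an explanation for the higher mitosis and replication lists in Zbtb32-/- arrays, a compressed signal range in some arrays would move all genes of a level alike. The level-matched lists had a median of 0.10 for mitosis and for replication, and both lists lay at percentile 100 of them. Both thus exceeded genes of like level. The percentiles do not allow for genes that vary together, and erythroid markers lay at 99.99, so they do not show how far chance could carry such lists. A lower share of plasma cells in the wild-type arrays would lower the plasma cell identity list as much. This assumes that lists of unlike level fall alike, which was not tested. The mitosis difference exceeded that of plasma cell identity by 0.24 (two-sided exact permutation p = 0.0238). It did so by 0.20 over replicates 1 to 3 and by 0.29 over replicates 4 to 6. Without Zbtb32-/- replicate 6 it did so by 0.22, where the exact p was 0.0606. Over replicates 4 to 6, plasma cell identity differed by 0.16, monocyte markers by -0.57 and T and NK markers by -0.40. These are the directions of such a lower share, but erythroid (0.19) and neutrophil markers (0.12) went the other way. Dilution as a part of the cause thus stays open. RNA of erythroid precursors cannot be told apart from a change in plasma cells: with the erythroid mean as covariate the mitosis difference was 0.237 (95% interval 0.020 to 0.454), which neither removes nor secures it. The erythroid marker with the highest value, Car1, averaged 9.18, and 1 of the 13 measured erythroid genes is in another list too. The CD138 and NP gate should remove such cells. Yet S100a9 averaged 12.55 and Ngp 12.25 although the sort excluded cells with Ly6g and CD11b, so the gate cannot decide this question. Of 100 splits of the arrays, 2 gave as small a camera p for mitosis, the real one included. The real camera p was 1.67e-18, against 8.42e-22 for the smallest other. Of 100 splits balanced over the replicate sets 2 did so as well, with the same other split, so this adds no separate evidence. A share of 2 in 100 makes chance less likely for this list taken alone but does not exclude it. Once 28 lists are counted, chance is not made unlikely (exact permutation adjusted p = 0.424). More cycling cells among Zbtb32-/- plasma cells may be a biological explanation that stays open.

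The 7 unnamed probe sets lower in Zbtb32-/- cells were weighed against RNA of other cells and chance. With the mean of the other cell type markers as covariate the mean difference over the 4 signals was -2.10 (95% interval -2.39 to -1.81). It was -2.12 without the covariate. That covariate joins the neutrophil, monocyte, erythroid and T and NK lists, which differed between genotypes by 0.22, -0.11, 0.27 and -0.21. Differences in opposite directions cancel in it, so it could hardly move the result. RNA of a single other cell type was not tested and stays open. Of 100 splits, 2 gave as many probe sets, the real one included, and the highest other split gave 7. Of 100 balanced splits only the real one did. Both shares lay under 5%, which makes chance less likely. That other split shared 4 of 6 arrays with the genotypes and 4 of 6 with the replicate sets. A strain variant beside the targeted gene and an effect of Zbtb32 itself stay open as untested, because the probe sets have neither a gene nor a position here.

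Probe sets that list immunoglobulin variable segments differed between arrays of a genotype more than other probe sets did. The median residual SD of 25 such probe sets was 0.847, against 0.214 for probe sets matched on level, a ratio of 3.95, and the highest of 10000 matched medians was 0.345. A small number of clones per array, each with its own variable segments, could give such a spread. Not all of these probe sets had it: probe sets 10438405 and 10438415, which list lambda segments, had residual SDs of 0.080 and 0.170. Several of the 25 also list constant regions. Differences in hybridisation between such segments were not tested, and 0 of the 25 differed between genotypes (limma smallest adjusted p = 0.0787, with 0 higher and 5 lower at an unadjusted p under 0.05).

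A count of 0 genes is reached by any split, so its 100 of 100 splits were fixed beforehand and bear on chance neither way (the highest other split gave 2). The 642 genes at an unadjusted p under 0.05 were matched by 44 of 100 splits and by 23 of 100 balanced ones, and the highest other split gave 2984, a sign of structure among the samples such as the difference between replicate sets. The 15 lists past camera's threshold were matched by 27 of 100 splits, with 20 in the highest other, and by 15 of 100 balanced ones, so chance was not excluded for that count.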

How the results depend on the processing

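Depth in the sense of counts does not apply to arrays, and signals near background limit genes of low level. The settings that use only some replicates, the sex and erythroid covariates, the setting without wild-type replicates 2 and 6, the replicate sets as a block and the test of all probe sets were chosen after the data were seen. Outside the set tests, the mitosis, replication, complex I and complexes II to V lists kept their direction under every alternative run. Their differences were 0.19 to 0.45, 0.16 to 0.32, 0.08 to 0.22 and 0.06 to 0.20. These lists also kept their camera call at the preset correlation. That setting gave a median of 11 lists in other splits of the arrays, so the kept call says little. With an estimated correlation 0 lists passed under any of these alternatives. Where a value below changed side or sign, the cause was not tested.

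With an estimated correlation, with fry and with the exact permutation test 0 lists passed. The differences stayed at 0.32 for mitosis, 0.25 for replication, 0.15 for complex I and 0.14 for complexes II to V under all 3, and the adjusted p for these 4 ran from 0.342 to 0.712. Counts of genes at an unadjusted p and at least 1.5-fold were 70 higher and 20 lower, over all probe sets 7 were lower, and 10 genes near Zbtb32 had an unadjusted p under 0.05. The lists past the threshold numbered 9 over replicates 1 to 3 and 15 over replicates 4 to 6. Over replicates 4 to 6 alone 1 gene passed, lower in Zbtb32-/- cells: Rny1, named after its value was seen, at -1.52 (limma adjusted p = 0.0253), with 0.16 over replicates 1 to 3. The other alternatives gave 10 to 16 lists, and leaving out single arrays gave 12 to 17, of which 9 lists passed in all 12.

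The replicate numbers were used as a block: 0 genes passed, 914 had an unadjusted p under 0.05, and the same 15 lists passed. The block left the differences at 0.32 for mitosis, 0.25 for replication and -0.11 for Zbtb32, and changed no other call. The same-numbered arrays deviated together with correlations from 0.02 to 0.47, not all above 0.1, and 2 of 6 wild-type arrays correlated best with their own number, so the numbers were not read as pairs. The deviations of arrays of opposite genotype from their genotype means correlated at 0.20 on average within replicates 1 to 3 or 4 to 6. Between these sets they correlated at -0.20. Such deviations cancel within each genotype, so the second average largely follows from the first and is no separate observation.

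Over replicates 1 to 3 the sign was opposite for Zbtb32 (0.021), the lists of autophagy (-0.013), B cell genes (0.038), MHC class II (0.15), monocytes (0.36) and plasma cell identity (-0.011), and for Bcl2 (-0.062), Atg14 (-0.014), Bpgm (-0.10), Ighg3 (0.17), Ciita (0.084), H2-Ab1 (0.071), Cybb (-0.046) and Cd2 (0.63). Over replicates 4 to 6 it was opposite for cell cycle inhibitors (0.049), immediate early genes (0.11), interferon-stimulated genes (-0.030), ND3 (-0.18), S100a9 (-0.23) and Ngp (-0.25). Median centring turned cell cycle inhibitors (0.020), immediate early genes (0.0044) and Cd2 (0.022). The filter at the 50th percentile turned memory B cell markers (0.076), and the mean of all probe sets turned the cell cycle inhibitors list shift (0.0024) and ND3 (-0.015). Array weights turned neutrophil markers (-0.034), Ighg3 (0.11), ND3 (-0.021) and Sparc (-0.31). The sex covariate turned Bpgm (-0.034) and Cd2 (0.0079), and the erythroid covariate turned the autophagy list shift (-0.0058). Without wild-type replicates 2 and 6 the sign was opposite for interferon-stimulated genes (-0.056), MHC class II (0.014), neutrophil markers (-0.13), ND3 (-0.064), S100a9 (-0.12), Ngp (-0.12) and Sparc (-0.25).

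Leaving out single arrays turned the following differences at 1 end of their range: immediate early genes (-0.12 to 0.052), interferon-stimulated genes (-0.026 to 0.097), cell cycle inhibitors (-0.050 to 0.048), MHC class II (-0.084 to 0.038), monocyte markers (-0.32 to 0.13), neutrophil markers (-0.12 to 0.44), stromal markers (-0.19 to 0.035), H2-Ab1 (-0.083 to 0.0070), Cybb (-0.0042 to 0.28), Bpgm (-0.14 to 0.16), Sparc (-0.31 to 0.48), Prss34 (-0.49 to 0.039), S100a9 (-0.16 to 0.24), Ngp (-0.17 to 0.61), ND3 (-0.13 to 0.31), Ighg3 (-0.23 to 0.0037) and Cd2 (-0.29 to 0.16). The G1, immediate early, monocyte, neutrophil, plasma cell identity and stromal lists, which did not pass camera on all 12 arrays, passed on leaving out certain arrays, such as wild-type replicate 2 for monocyte markers (-0.32), Zbtb32-/- replicate 3 for neutrophil markers (0.44) and Zbtb32-/- replicate 6 for stromal markers (-0.19). These calls used the preset correlation, and with an estimated one 0 lists passed on leaving out any single array. In all, 229 alternative values of the main results and 2920 of the other results kept their direction and their side of the threshold. The other results are mostly single genes named by the fixed rule, none of which passed in any setting. Their side of the threshold could thus hardly change, and most settings share nearly all arrays, so this tally does not measure robustness. Of the main results 9 counts moved, 12 values lost their call and 1 turned, and of the others 55 lost a call, 27 gained a call and 86 turned.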

Other observations

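All tests in this part were chosen after the data were seen. Xist, the transcript that silences an X chromosome in female cells, was 11.48 in Zbtb32-/- replicate 2 and 11.22 in Zbtb32-/- replicate 3, 8.87 in wild-type replicate 2 and at most 5.93 in the other 9 arrays. The Y-linked Eif2s3y was 6.40 and 5.62 in the first 2 of these arrays and 7.53 in wild-type replicate 2, where it lay between 7.01 and 8.16 in the other arrays. Wild-type replicate 2 thus held transcripts of both kinds.

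Replicates 1 to 3 and replicates 4 to 6 differed in 943 genes at an adjusted p under 0.05 with limma and in 3821 at an unadjusted p under 0.05, where the genotypes gave 0 and 642. The mitosis list was lower in replicates 4 to 6 by a difference of -0.19. With these sets as a block, 8 probe sets of the whole table passed between genotypes, 7 of them lower in Zbtb32-/- cells, and these included all 7 that passed without it. The probe sets that name several genes gave 0 calls between genotypes (limma smallest adjusted p = 0.866, with 55 higher and 15 lower at an unadjusted p under 0.05).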
